A study of Arabidopsis thaliana with 4 samples.

How the data were processed

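Gene expression was measured on 4 Affymetrix ATH1 arrays, which carry probe sets of short oligonucleotides for most annotated Arabidopsis thaliana genes. Each array held biotin-labelled target made from total RNA of whole rosettes of 46-day-old plants in the C24 background that carry an inducible ORS1 overexpression construct. The labels put 2 arrays in the DEX group (rosettes sprayed with 30 µM dexamethasone) and 2 in the mock group (0.05% ethanol), all harvested 5 h after spraying. They call the arrays biological replicates without giving the number of plants behind each. The p-values therefore speak for these samples only, and how much of the spread between plants they cover is not known.

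The deposited values are log2 expression values, one per probe set and array. The submitters' processing notes name GCRMA, which corrects the background using probe sequence, applies quantile normalization and combines the probes of a set by median polish. Its version and settings are not given in the sources used here. The table does not state its scale, and log2 was taken from GCRMA and from the values, which ran from 2.59 to 13.62 with array medians of 6.51, 6.54, 6.55 and 6.51 for DEX replicates 1 and 2 and mock replicates 1 and 2. No further normalization was applied. GCRMA shrinks differences between dim probe sets, so folds near the floor are understated.

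Of the 22810 probe sets, 64 Affymetrix controls were left out, and 2863 others were removed because fewer than 2 arrays reached a log2 value of 4. The remaining 19883 were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) for DEX against mock with no covariate, two-sided. Here eBayes draws each variance toward a trend fitted over all probe sets, so SEs and p-values rest largely on that pooled spread. SDs are those of each pair of arrays. Adjusted p-values are Benjamini-Hochberg values over the 19883 probe sets, and a probe set under 0.05 is called, that is, said to have risen or fallen. With 2 arrays per group the model has 2 residual degrees of freedom, and the number of arrays limits the precision. Because of that, probe sets were also counted whose lowest value in one group lay at least 1 log2 unit (2-fold) above the highest in the other.

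Gene names came from the platform annotation, with symbols updated through the RefSeq table of assembly TAIR10.1. The annotation used here lists 14016 of the 22746 non-control probe sets: 13513 have 1 gene, 503 have several, and 8730 are unlisted here, which does not mean that they lack a gene. Names were printed only for probe sets with 1 gene. No genome build goes with the expression table, so no coordinates are given. Gene length, used in checks of the arrays, is the span of the gene in the RefSeq table and was available for 11311 tested nuclear genes.

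The rule for named genes took the 15 largest rises and the 10 largest falls among probe sets with 1 gene, an adjusted p under 0.05 and non-overlapping groups. It also took up to 4 members of each of 22 gene lists. The lists held 333 entries and 324 distinct genes, of which 44 had a tested probe set with 1 gene. They were NAC factors, senescence-associated genes, nucleases and proteases of senescence, chlorophyll breakdown, photosynthesis, hydrogen peroxide and redox, abscisic acid, salicylic acid and defence, jasmonate, ethylene, auxin, cytokinin, cell wall loosening, nutrient remobilisation, the circadian clock, heat shock, touch with wounding and cold, markers of floral, root, guard cell and vascular tissue, and reference genes. A gene with several probe sets entered once, by the one with the highest mean. The 3 lists with at least 5 tested members were tested with camera (limma, preset inter-gene correlation of 0.01), which compares a list with other genes, and again with an estimated correlation. With an estimate, camera rests on the 2 residual degrees of freedom, so a miss there can come from the few arrays alone. Beside it fry tested whether a list's genes move one way on balance. Groups, tests, lists and the alternatives were fixed before the data were examined, except where the closing section says otherwise.

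The test was tried on simulated data with the measured means of the 19883 probe sets, of which 200 were changed. It recovered 4.48% of the probe sets changed 1.5-fold, 49.3% of those changed 2-fold and 100% of those changed 4-fold, with 3 false calls among 105. Spreads were drawn from the distribution of variances that limma fitted, with independent normal noise, equal in both groups. Differences between whole arrays, such as a gene length trend, were not simulated, so these rates may be better than those in the data. Alternatives covered the filter, quantile normalization, equal array medians, the variance model, the threshold, a block for the replicate number, probe sets prone to cross-hybridisation, and leaving out each array. With an array left out 1 group holds 1 array, so the spread is estimated from the other pair alone and the single array is assumed to vary like it. Removal of each array's trend on gene length was added after the data were seen. Plots were drawn with matplotlib 3.10.9.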

Results

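ORS1 (AT3G29035) is a NAC-family transcription factor of Arabidopsis known as a promoter of leaf senescence. The series asks which genes change in rosettes shortly after ORS1 is switched on. Dexamethasone (DEX), a steroid that activates the inducible construct, was sprayed on 46-day-old plants, and mock plants carrying the same construct received 0.05% ethanol. Rosettes were harvested after 5 h, and 2 ATH1 arrays were measured per group. All 4 samples came from plants with the construct, so a response to DEX itself was not measured apart from a response to ORS1.

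No probe set used here was paired with ORS1, nor with its neighbours AT3G29030 (EXPA5) and AT3G29040. The level of the induced gene, and with it a check of the labels, was therefore not analysed here. The largest rise of any non-control probe set in the table was 4.39-fold.

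Most changes that passed the test 5 h after DEX were of a few fold. Transcripts of AT1G56060 rose 4.02-fold, the glucosyltransferase gene UGT76B1 3.18-fold, OSM34, an osmotin-like gene, 3.13-fold and the plant defensin gene PDF1.4 3.02-fold. Transcripts of JAL23, a jacalin-related lectin, fell to levels 3.53-fold lower, those of the sucrose transporter SWEET13 2.95-fold lower, and those of MYC4, a transcription factor of jasmonate signalling, 2.39-fold lower. In all, 49 probe sets rose and 40 fell at an adjusted p under 0.05 (limma, n = 2 arrays per group), and on all 89 the groups did not overlap. Of the 49, 22 belonged to 1 gene, 2 to several and 25 were unlisted; of the 40, 16 belonged to 1 gene and 24 were unlisted.

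Among the named rises, AT1G56060 had a log2 change of 2.01 ± 0.20 (SE; adjusted p = 0.0073) and AT4G01870 of 1.93 ± 0.17 (adjusted p = 0.00552). OSM34 stood at 7.64 ± 0.029 (SD, n = 2) after DEX and 5.99 ± 0.025 after mock, a difference far larger than the spread of either pair. UGT76B1, whose product adds glucose to small defence-related molecules, rose by 1.67 ± 0.18 (SE; adjusted p = 0.00977). MSRB9, a methionine sulfoxide reductase, rose from 7.31 ± 0.31 to 8.90 ± 0.066 (SD, n = 2; limma adjusted p = 0.022). AT5G64120, a class III peroxidase gene, rose by 1.54 ± 0.22 (SE; adjusted p = 0.0295) and CCOAMT, a caffeoyl-CoA O-methyltransferase, rose 2.47-fold (adjusted p = 0.015).

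AT4G15700, a glutaredoxin gene, rose by 1.57 ± 0.12 (SE; adjusted p = 0.00516), with mock values of 3.77 and 3.85 under the filter level of 4. Near-identical glutaredoxin genes lie beside it on the chromosome, so signal shared with them cannot be ruled out. The other named rises of this group were AT1G49500, AT1G19020, AT2G44380, PDF1.4, AT2G32190, AT3G61930 and AT3G13950, with log2 changes of 1.35 (AT3G13950) to 1.99 (AT1G49500) and adjusted p-values of 0.00977 (AT2G44380) to 0.0478 (AT1G19020). AT1G49500 and AT1G19020 rested on the least even mock pairs, with SDs of 0.71 and 0.70.

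**Figure D1:**
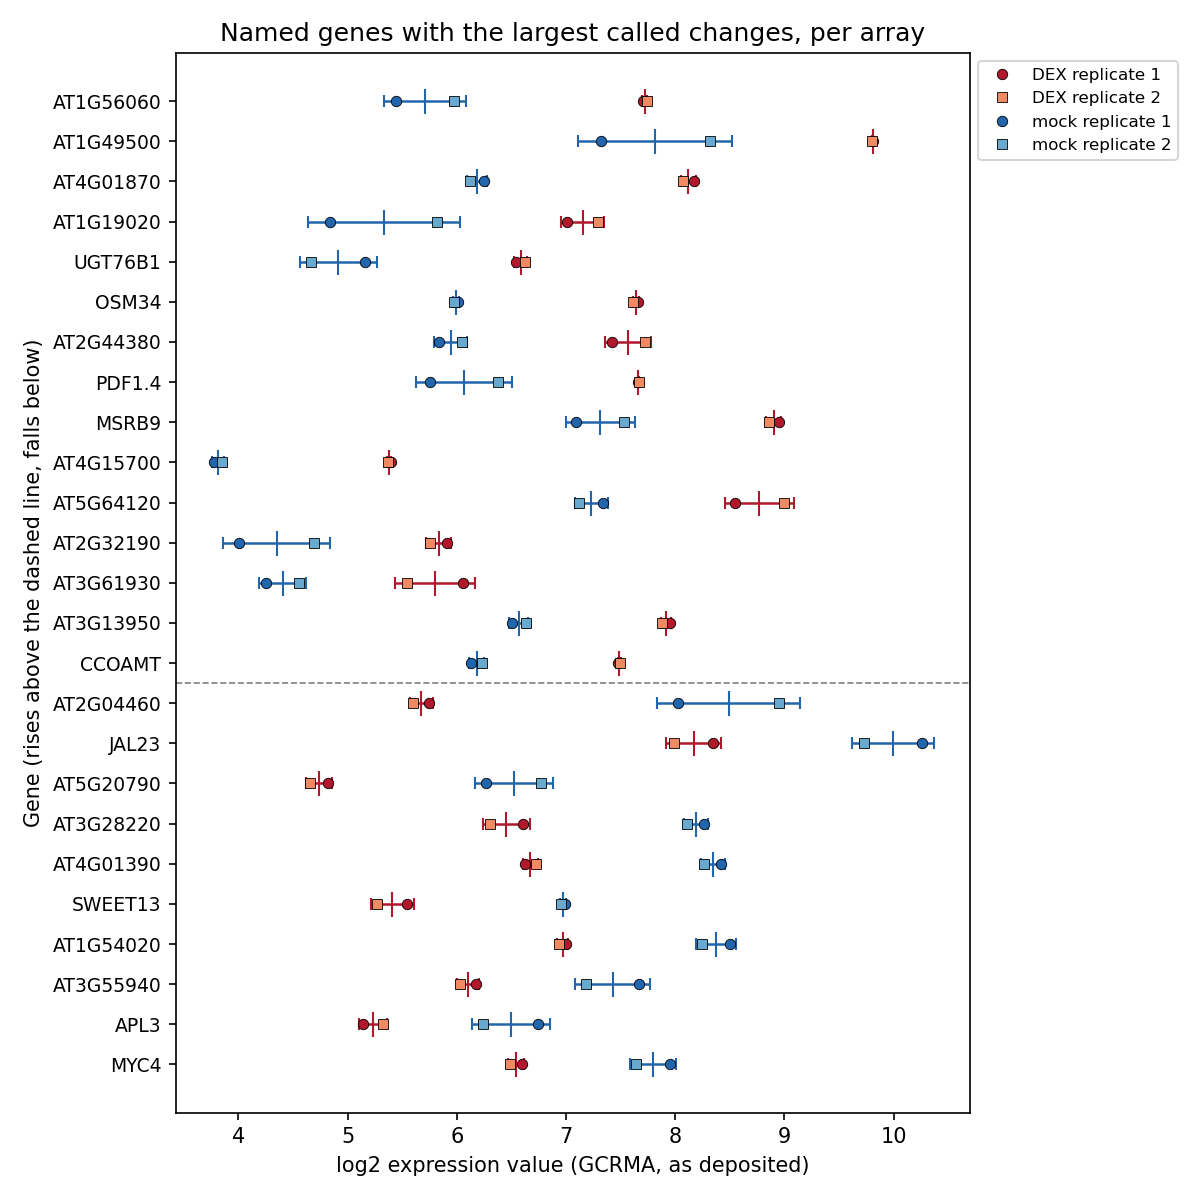
Log2 expression value (x axis) of the 15 named genes with the largest rises (above the dashed line) and the 10 with the largest falls (below it), 1 symbol per array; long ticks and bars give the mean and SD of each pair (n = 2). For every gene both DEX arrays lie on one side of both mock arrays, and the mock arrays of AT1G49500, AT1G19020 and AT2G04460 lie far apart.

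The largest fall of a named gene was that of AT2G04460, with a log2 change of -2.81 ± 0.28 (SE; adjusted p = 0.0073), or 7.03-fold. JAL23 fell by 1.82 ± 0.25 (SE; adjusted p = 0.0232), from 9.99 ± 0.38 to 8.17 ± 0.25 (SD, n = 2). SWEET13 fell by 1.56 ± 0.16 (SE; adjusted p = 0.0073). APL3, a large subunit of the ADP-glucose pyrophosphorylase of starch synthesis, had a log2 change of -1.26 ± 0.19 (SE; adjusted p = 0.0371). AT3G28220 and AT4G01390, both TRAF-like genes, had changes of -1.74 and -1.67, with adjusted p-values of 0.00954 and 0.00929. The remaining falls of this group were AT5G20790 (3.44-fold), AT1G54020, a GDSL-type lipase gene (2.65-fold), AT3G55940, a phosphoinositide phospholipase C gene (2.51-fold), and MYC4 (2.39-fold; adjusted p = 0.0317).

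Other probe sets of 1 gene passed with smaller changes. Rises were measured for AT4G16260, a glycosyl hydrolase gene (2.32-fold), BGLU27 (2.26-fold), AT3G01830 (2.16-fold) and AT4G39670 (2.09-fold). The calmodulin-like gene CML37 (1.87-fold) rose too, as did AT1G10585, which lay between AT4G16260 and BGLU27. AT4G16260 passed narrowly (limma adjusted p = 0.0495) and missed with no filter or with quantile normalization (adjusted p = 0.0585 and 0.0564). Both mock values of CML37 and AT1G10585 were under 4, where differences are understated. With the gene length trend of the arrays removed, CML37 was at 0.76 and no longer passed (adjusted p = 0.0837). Falls were measured for AT2G21560 (2.22-fold), DFR, an enzyme of anthocyanin synthesis (2.21-fold), iqd33, a calmodulin-binding IQ-domain gene (2.17-fold), AT4G23000 (2.03-fold) and AT1G55760, the smallest of them. The largest rises and the largest fall lay on unlisted probe sets, picked out here after their values were seen: 267567_at and 263948_at rose by 2.14 and 2.08 log2 units, and 262369_at had a change of -3.15. AT2G04460 came next among the falls, before the unlisted 258856_at at -2.78. At an unadjusted p under 0.05 there were 1745 probe sets, where chance would give 994.

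Without the variance model, counting probe sets at least 2-fold apart on both arrays of each group, 42 were higher and 31 lower after DEX. Splitting the arrays by replicate number gave 0 probe sets higher in replicate 1 and 12 lower, and the remaining split gave 0 and 0. Of those 12, 7 were plastid-encoded, among them psbC, psbE and psbF. The groups did not overlap for 38.0% of probe sets, where chance gives 33.3%, against 32.0% and 29.6% in the other splits. A probe set without ties separates in exactly 1 of the splits, so these shares are tied to each other. The other splits are thus no independent reference for them.

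Counts depended on the arrays and the variance model: without DEX replicate 1 there were 112 rises and 50 falls, without DEX replicate 2 118 and 72, without mock replicate 1 127 and 101, and without mock replicate 2 1803 and 1388. Without an intensity trend 27 rose and 24 fell, robust empirical Bayes gave 80 and 59, and an unmoderated variance gave 0 of either, with 1297 probe sets at an unadjusted p under 0.05. Of the named genes, AT4G16260, DFR and SWEET4 lost their call without DEX replicate 1, AT4G16260, DFR, AT5G64120, AT1G54020, MYC4 and AT4G23000 without DEX replicate 2, and AT3G61930, AT1G10585 and AT4G39670 without mock replicate 1, with adjusted p-values of 0.0513 (AT4G39670) to 0.295 (AT4G16260).

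**Figure D2:**
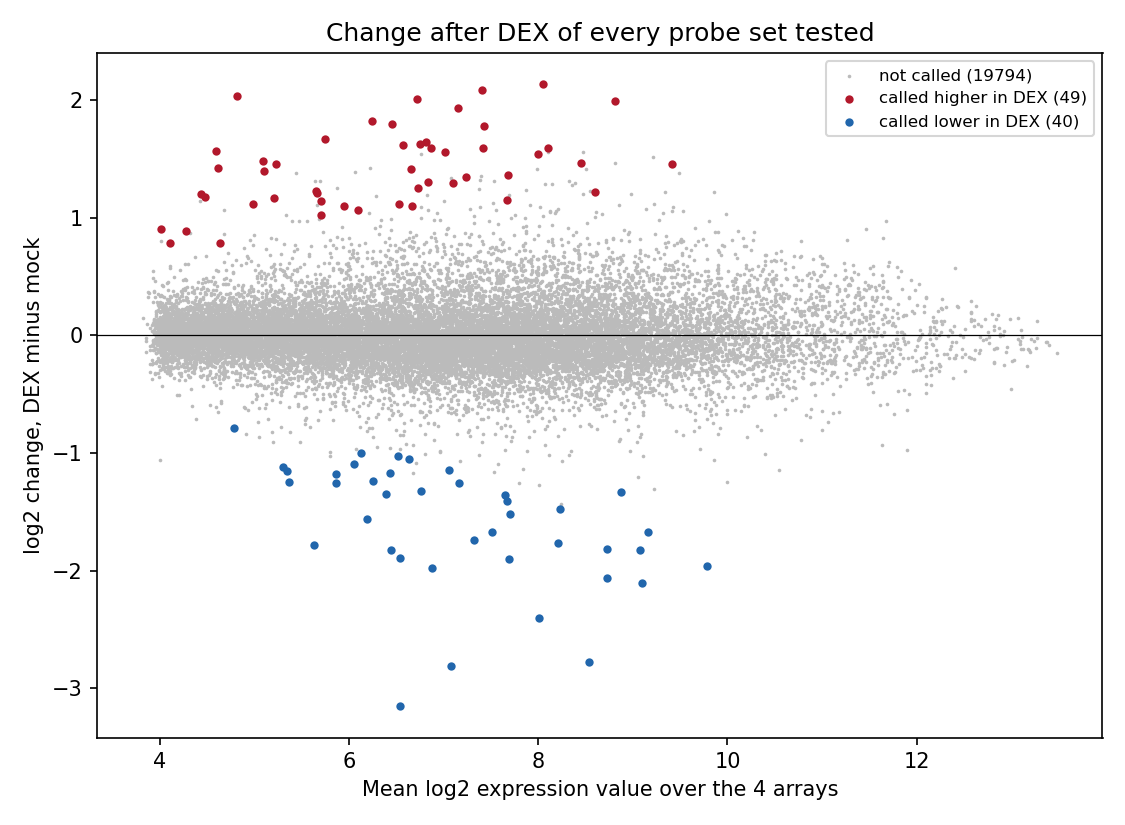
Log2 change, DEX minus mock (y axis), against the mean log2 expression value over the 4 arrays (x axis) for the 19883 probe sets tested; red and blue points are the 49 and 40 at an adjusted p under 0.05 (limma). Changes reach 2.14 upwards and -3.15 downwards, and the called probe sets span dim to bright signal.

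Senescence-associated genes had small positive changes. All 6 tested members of the 25 listed had positive log2 changes, with a median of 0.24, and none passed over all probe sets. WRKY53, a transcription factor that promotes senescence, had a change of 0.64 ± 0.18 (SE) and passed when adjusted over the list alone (adjusted p = 0.0361), whereas WRKY6 (0.39 ± 0.14) and WRKY22 (0.28 ± 0.12) did not (adjusted p = 0.0712 and 0.112). SAG29, APG8A (ATG8A) and SAG101 had changes of 0.20, 0.11 and 0.030. The sign of the last 2 depended on single arrays: APG8A turned to -0.29 without mock replicate 1, and SAG101 to -0.18 without mock replicate 2 and -0.070 without DEX replicate 1. As a list the 6 genes ranked higher than other genes (camera adjusted p = 0.00887), but missed 0.05 with an estimated correlation (adjusted p = 0.279). The estimate was -0.0659, so that miss came from the 2 residual degrees of freedom and not from correlated genes. In fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, the list did not pass (adjusted p = 0.0738). In camera it also missed 0.05 without DEX replicate 1, mock replicate 1 or mock replicate 2 (adjusted p = 0.0819, 0.0702 and 0.0771), with a range of 0.00589 to 0.279 over all alternatives.

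Genes of the photosynthetic machinery did not pass, singly or as a list. Of 37 listed, 6 were tested (LHCB4.1, LHCB4.2, PSAN, PSBW, PSBY and RCA), and 0 passed, over all probe sets or adjusted over the list alone. Their median was -0.038, and the list did not stand apart (camera adjusted p = 0.968; 0.971 with an estimated correlation), its direction turning under quantile normalization and equal array medians. PSAN had a change of 0.13 ± 0.16 (SE) and RCA, the activase of Rubisco, of -0.11 ± 0.15. LHCB4.1 (13.33 to 13.42) and RCA (13.15 to 13.41) lay close to the array maxima of 13.37 to 13.62, where differences may be understated. NOL was the 1 tested gene of the 10 for chlorophyll breakdown, and its change of -0.17 ± 0.19 did not pass.

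Genes of cell wall loosening went both ways. Of 15 listed, 5 were tested, and XTH18, a xyloglucan endotransglucosylase/hydrolase, rose by 0.89 ± 0.13 (SE; adjusted p = 0.0311), with both mock values under 4. Adjusted over the list alone, XTH18 and XTH33 (0.66 ± 0.14) passed as higher, and XTH19 (-0.36 ± 0.14) and the expansin EXPA4 (-0.49 ± 0.20) as lower. EXPA8 had a change of 0.66 ± 0.33 and did not pass. The list as a whole did not pass (camera adjusted p = 0.114; 0.318 with an estimated correlation), although without DEX replicate 1 or DEX replicate 2 it did (adjusted p = 0.000333 and 0.0271; 0.402 at most). In those fits the DEX group is 1 array and the spread comes from the mock pair alone.

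Of the genes of nutrient remobilisation 3 of 15 were tested, among them sugar transporters of the SWEET family. SWEET4 fell by 1.17 ± 0.17 (SE; adjusted p = 0.0311), SWEET11 (-0.62 ± 0.18) passed adjusted over the list alone (adjusted p = 0.0129), and PPDK (-0.42 ± 0.23) did not pass. Of the nucleases and proteases, 2 of 12 were tested, and GAMMA-VPE, a vacuolar processing enzyme, had a change of -0.93 ± 0.22 that passed adjusted over the list alone (adjusted p = 0.00597) and not over all probe sets (adjusted p = 0.19). ALPHA-VPE was at -0.082 ± 0.15.

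Of the hormone lists, the one for auxin response had 4 of 10 members tested. GH3.3, an enzyme that conjugates auxin to amino acids, had a change of 0.76 ± 0.18 (SE) and IAA29 one of 0.47 ± 0.16. Both passed adjusted over the list alone (adjusted p = 0.011 and 0.0391) and neither over all probe sets (adjusted p = 0.186 and 0.413). Among the 11311 genes with a length, GH3.3 passed once the length trend was removed (0.83, limma adjusted p = 0.0209). With a replicate block it passed too (limma adjusted p = 0.00847), but in no other setting that kept all 4 arrays. GH3.1 and WES1 (GH3.5) had changes of 0.31 and 0.027. The 3 tested of 21 abscisic acid and dehydration genes, COR47, COR15A and COR15B, had changes of -0.51, -0.51 and -0.41, and none passed. No gene passed among PDF1.2 of the jasmonate list (0.36 ± 0.23; 1 of 22 tested), EIN3 of the ethylene list (-0.33 ± 0.24; 1 of 19 tested), and ARR15 and RR16 (ARR16) of the cytokinin list (0.29 ± 0.18 and 0.36 ± 0.19; 2 of 10 tested). These outcomes hung on the mock pair. Without mock replicate 1, GH3.3, COR15A and COR15B passed over all probe sets, and PDF1.2 turned to -0.024. Without mock replicate 2, GH3.3, IAA29, COR47, PDF1.2, EIN3 and RR16 passed, and COR15A and COR15B shrank to -0.23 and -0.015. Such passes carry little weight, because the mock group is then 1 array and the spread comes from the DEX pair alone. Of the 44 tested genes of all lists, 16 newly passed without mock replicate 2, the reference genes AT2G28390 and PEX4 among them.

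For hydrogen peroxide and redox, 3 of 27 genes were tested and 0 passed: STZ (ZAT10), a zinc finger repressor, was at 0.60 ± 0.24 (SE), NDB2 at 0.16 ± 0.21 and AT2G21640 (UPOX) at 0.076 ± 0.19. STZ was also the 1 tested gene of the 11 for touch, wounding and cold, and a list of 1 gene needs no adjustment of its own; over all probe sets STZ did not pass (adjusted p = 0.529). GI of the circadian clock (1 of 15) was at -0.28 ± 0.22 and ATHSP22.0 (HSP22) of heat shock (1 of 13) at -0.034 ± 0.13. Among tissue markers, FMA (FAMA), a guard cell regulator and the 1 tested of 3, was at -0.47 ± 0.19 and did not pass over all probe sets (adjusted p = 0.511), and EXPA7 of the root list (1 of 3) was at -0.13 ± 0.15. The reference genes AT4G34270 (TIP41), AT2G28390 (SAND) and PEX4 (UBC21), 3 of 10 tested, were at 0.017, -0.30 and 0.32, and none passed. The lists of 23 NAC factors, 18 salicylic acid and defence genes, 8 floral and 6 vascular markers had 0 tested members paired with 1 gene here.

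The arrays differed from one another in ways the groups do not describe. The DEX arrays differed by an SD of 0.21 log2 units over the probe sets and the mock arrays by 0.37. Across the 11311 genes with a length, which are not independent replicates, the difference of mock replicate 1 to mock replicate 2 rose with log2 gene length (Pearson r = 0.534, Spearman rho = 0.594), whereas that of the DEX arrays did not (r = -0.036). With the genes in 5 equal groups by length, mock replicate 1 deviated from the mean of the 4 arrays by a median of -0.17 in the shortest group and 0.18 in the longest. The median DEX-minus-mock change ran from 0.10 in the shortest group to -0.083 in the longest. In the actin, GAPDH and ubiquitin controls, the 3' minus 5' signal was highest on DEX replicate 1 in 6 of 6 pairs, for ubiquitin 1.22 against 0.74 on DEX replicate 2 and 0.82 and 0.71 on the mock arrays. Separately, the 25S rRNA control stood at 7.38 and 7.35 on replicate 1 of DEX and mock and at 9.64 and 8.86 on replicate 2, and the median of 64 plastid-encoded probe sets at 7.44 and 7.43 against 8.35 and 8.12. Of these 64, 0 passed for DEX against mock (limma; smallest adjusted p = 0.772).

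**Figure D3:**
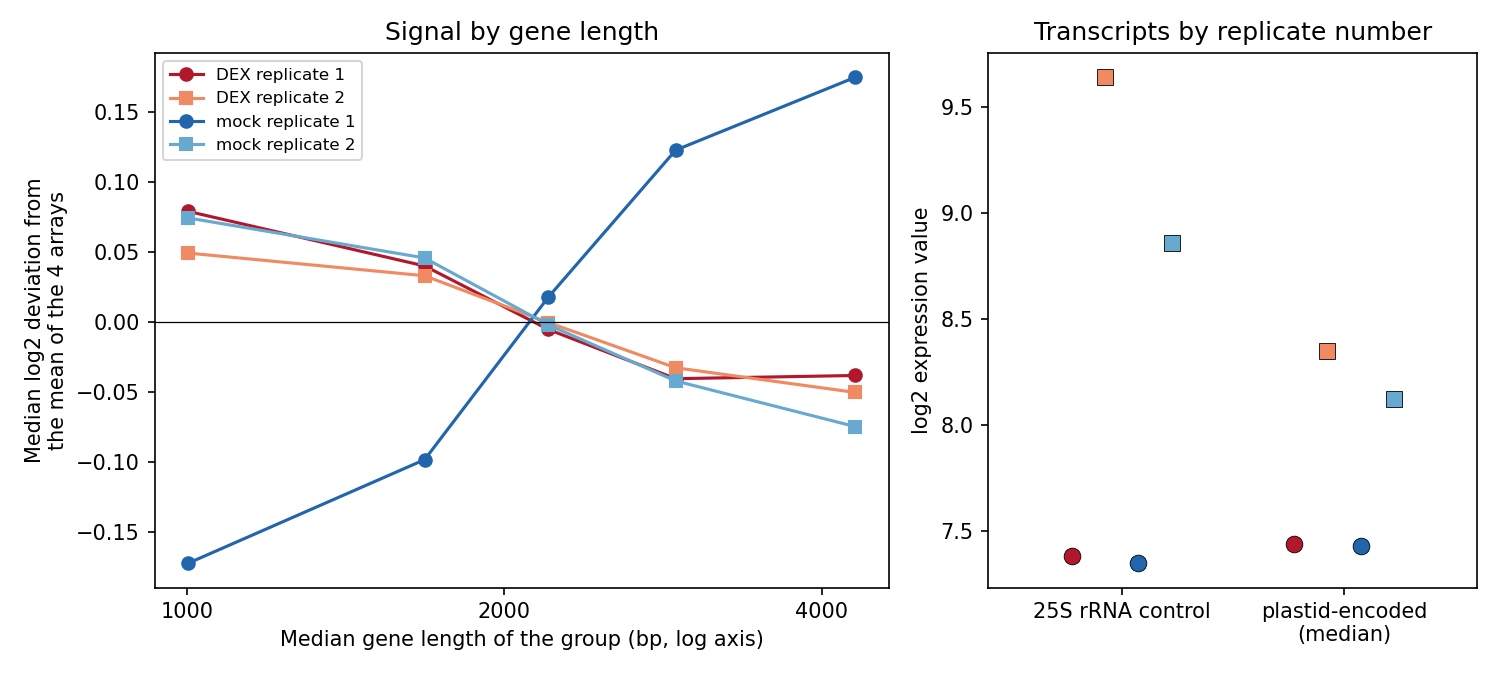
Left, median log2 deviation from the mean of the 4 arrays (y axis), 1 line per array. Genes are in 5 equal groups by length (x axis, median length in bp, log axis). Mock replicate 1 runs from -0.17 to 0.18. The mean includes mock replicate 1, so the slight decline of the other arrays follows largely from its rise. Right, log2 expression value of the 25S rRNA control and the median of the 64 plastid-encoded probe sets, 1 symbol per array; both replicate 2 arrays lie above both replicate 1 arrays.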

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

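The removal of the gene length trend and the fit to genes with a length were added after the data were seen; the other settings here were fixed before. All 89 called probe sets kept their direction in each setting in which they were tested, which in most settings was fixed in advance. Their groups do not overlap, so leaving out an array cannot turn a sign. Changes of the filter, the variance model or the block leave the log2 change as it was. Equal array medians adds the same small amount to every change and moved the median over all tested from -0.012 to 0.00279. With smallest called changes of 0.78 and -0.79, that could not turn a sign. Only quantile normalization and removal of the length trend shift probe sets by differing amounts, so the kept directions say little. Of 97 named genes and probe sets, none changed sign in a setting where either value was called. Of the 42 of these that were called, 23 stayed called without an intensity trend, 32 with no filter, 37 with quantile normalization, 40 with equal array medians and 0 with an unmoderated variance; leaving out 1 array kept 36 to 42. Against 49 rises and 40 falls, the counts were 27 and 24 without an intensity trend, 80 with robust empirical Bayes (59 falls), 107 and 81 at an adjusted p under 0.1, and 0 and 0 with an unmoderated variance, which estimates each spread from 2 residual degrees of freedom. Leaving out 1 array gave 112 to 1803 rises and 50 to 1388 falls. The highest counts came without mock replicate 2. The spread rests on the DEX pair without mock replicate 1 too, and the cause was not tested. No other filter, scaling or exclusion of cross-hybridising probe sets moved the counts of rises and falls by over 1.5 times.

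The count of 2-fold higher and lower probe sets, 42 and 31, became 168 and 118 at 1.5-fold and ran from 55 to 338 and from 39 to 78 with 1 array left out; without mock replicate 2 it was 338 and 78, and without DEX replicate 2 the lower count was 52. The 1 list past its threshold became 0 with camera's estimated correlation, 0 in fry, which asks another question, and 0 to 2 with 1 array left out: 0 without mock replicate 1 or mock replicate 2 and 2 without DEX replicate 2. Without DEX replicate 1 it was also 1, but another list, cell wall loosening in place of senescence. Among genes with a length, 11 rises and 9 falls became 72 and 56 with the length trend removed, and 19 of the 20 stayed called. Of the 38 calls with a length, 20 passed when these genes were tested alone and 36 after the removal; XTH18 missed already without it (adjusted p = 0.0504).

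The labels number the replicates without saying what a number shares. Over the tested probe sets, same-numbered deviations from the group means correlated only weakly (0.108). Even so, 25S rRNA and plastid-encoded transcripts followed the number in both groups, and 2 pairs cannot settle what it stands for. With a replicate block 438 probe sets rose and 237 fell, all 89 among them. The median SE was 0.202 against 0.18 and residual degrees of freedom fewer, so the added calls show no sharper contrast. The 2 lists senescence and cell wall loosening passed (adjusted p = 0.0225 for each). Within both same-numbered pairs, 2-fold counts were 58 and 39. Robust empirical Bayes was not run for the lists, since camera takes no such option. The alternatives for ORS1 gave no value, as no probe set was paired with it. Signal over background limits dim probe sets: 12.6% to 13.9% of probe sets per array lay under the filter's log2 value of 4.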

Other observations

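The tests in this part were chosen after the data were seen, except that the bounds for the length trend in 9 of the 10 gene families, all but TBL, and for nuclear photosynthesis genes were set before their results. Genes that share a symbol were grouped into families, and the 38 families with at least 5 tested members were compared with other genes (limma's camera, preset correlation). At an adjusted p under 0.05, 9 families passed, and 0 with an estimated correlation (adjusted p = 0.837 for each). That form rests on the 2 residual degrees of freedom, so its misses cannot be put down to correlated genes alone. The 7 calmodulin-like CML genes all had positive changes, with a median of 0.37 (adjusted p = 5.99e-05) that dropped to 0.092 without mock replicate 1; CML37 passed by itself, and CML41 had a change of 1.46 ± 0.25 (SE) that did not (adjusted p = 0.0598). Of 6 WRKY genes 5 were positive (median 0.33, adjusted p = 0.0356), of which WRKY53, WRKY6 and WRKY22 also stand in the senescence list; WRKY47 was at 0.44 ± 0.16 and WRKY20 at -0.31 ± 0.17. Of 15 calmodulin-binding IQD genes only 4 were positive (median -0.22, adjusted p = 0.0156; -0.105 without mock replicate 1), with iqd33 called by itself.

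Families of short genes were also among those that ranked higher: the genes named PDF, which are defensins and the peptide deformylases PDF1A and PDF1B (7 of 7 positive, median 0.36), RALFL peptides (6 of 7, 0.30), PRA genes (10 of 11, 0.26) and NRPB polymerase subunits (6 of 6, 0.27), with adjusted p-values of 0.0302 to 0.0423. TBL genes (4 of 21 positive, median -0.090) and TRM genes (3 of 13, -0.18) ranked lower, with adjusted p-values of 0.0356 and 0.0198. TBL26 was at -1.03 ± 0.21 (SE; adjusted p = 0.108). The signs of all 9 medians held under quantile normalization and equal array medians, but these settings moved the medians little, so that says little. Without mock replicate 1 the medians of PDF and NRPB turned to -0.024 and -0.016. Those of RALFL, PRA, TBL and TRM shrank to 0.077, 0.038, -0.032 and -0.115. LSM genes just missed the threshold (adjusted p = 0.0527). The 13 SWEET genes did not shift as a family (median 0.038, adjusted p = 0.29), although SWEET13 and SWEET4 fell.

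The first pattern is the length trend of mock replicate 1. An effect of DEX on long and short genes is argued against, since the DEX arrays did not differ from mock replicate 2 along gene length (larger r = 0.0459). Degraded RNA or shorter labelled product on mock replicate 1 is argued against by the actin, GAPDH and ubiquitin controls, whose 3' minus 5' signal on mock replicate 1 minus mock replicate 2 ran from -0.67 to 0.107 log2 units over 6 control pairs; the signal was highest on DEX replicate 1 in all 6. Of the 20 called genes with a length, 95.0% stayed called with the trend removed, which was nearly assured. The smallest changes among the 89 calls were 0.78 and -0.79, against medians of 0.10 to -0.083 over the length groups. The removal also lowered the median SE from 0.175 to 0.155. By size the trend is not the whole cause of those calls, and only 38 of the 89 called probe sets have a length here. What made the array differ stays open, and no biological explanation was tested. The controls were read only for a higher 3' minus 5' signal on mock replicate 1. Whether a lower one, with differences reaching -0.67, goes with the trend was not tested.

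The second pattern is that plastid-encoded transcripts followed the replicate number, being higher in replicate 2 for 62 of 64 probe sets in DEX and 59 of 64 in mock. A difference of like size in all RNA without poly(A) tails in the labelled target is argued against by 22 mitochondrial probe sets. Their medians of 0.13 and 0.20 were at most 0.29 of the plastid-encoded ones (0.76 and 0.70). These medians too were higher in replicate 2 of both groups, so a difference of unequal size is not excluded. A difference limited to plastid and ribosomal RNA may remain, since the 25S rRNA control was also higher in replicate 2 of both groups, by at least 1.51 log2 units, but nothing here tests it independently. A difference in plastid gene expression between the plants is not decided: the median of 6 nuclear photosynthesis genes in replicate 2 minus replicate 1 was -0.011 in DEX and 0.157 in mock. Each group holds 1 array of each number, so this pattern does not separate DEX from mock.

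The third pattern is the family shifts, for which the length trend of mock replicate 1 is a candidate explanation because most families that ranked higher are of short genes. With the trend removed, PDF, PRA and RALFL kept 0.468, 0.335 and 0.35 of their median and no longer passed (adjusted p = 0.137, 0.243 and 0.243) because their medians dropped to 0.17, 0.085 and 0.10, with SDs over members of 0.541, 0.14 and 0.289 before and 0.524, 0.145 and 0.287 after, in line with the trend as their cause. WRKY kept 0.988 and still passed (camera adjusted p = 0.0366), but the removal was no real test there. WRKY genes are long (median 3072 bp), and the groups of longer genes had median changes of -0.0695 and -0.083. The trend thus runs against a rise in WRKY. EXPA and GSTU newly ranked lower (medians -0.21 and -0.20, adjusted p = 0.0446 and 0.0233). For CML (0.535) and IQD (0.731), which still passed, and for NRPB (0.697), TRM (0.538) and TBL (0.514), which did not, the values lie between the bounds and the trend cannot be told apart from a change after DEX; LSM (0.799) had not passed before, so its test decides nothing. Without mock replicate 1, 0 of the 38 families passed, WRKY, CML and GSTU coming closest (adjusted p = 0.0633 for each), though the WRKY median stayed at 0.33 while the CML median dropped to 0.092.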
